A study of Mus musculus with 4 samples.

How the data were processed

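Per the labels, small RNA was sequenced after RNA immunoprecipitation (RIP) for Argonaute2 (AGO2) from the olfactory bulb of C57BL/6 mice, 8 weeks after injection of the viral vector LV.PGK.GFP-AGO2 or after a sham injection. Per the protocols given, tissue was taken fresh and homogenised at once, RNA was extracted with the miRNAeasy Micro Kit, and libraries were made with the NEBNext Multiplex Small RNA Library Prep Set. The antibody, the injection site, the sequencing instrument and any separate input or unbound RNA are not given in the sources used here. It is therefore open whether the Control libraries hold RNA bound to the mouse's own AGO2 or only background of the procedure. The labels put 2 libraries in each group, with the replicate numbers 1 and 3 in both.

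The deposited table holds whole-number counts per mature miRNA name, and per the file headers these counts were made with featureCounts v1.4.6-p1 on primary alignments over the mature miRNAs of a mouse miRNA annotation for mm10. Per the submitters' processing notes, cutadapt and STAR were used and the genome build was mm10; their versions are not given in the sources used here. The counting command in the file headers carries no strand option and no option to count reads that overlap more than 1 name. The table has 1900 names at 2035 genomic positions, and 77 names have more than 1 position. Of the 1900 names, 794 had no count in any library. In the table, 75 names overlap another name, and 64 of these had no count in any library, against 730 of the 1825 other names. The largest count of an overlapping name without a free position was 17. MiR-24-3p, miR-126a-3p, miR-338-3p, miR-219a-5p, miR-142-3p and miR-30e-3p, which all overlap another name, were listed at 0 in the 4 libraries, although miR-30e-5p from the same hairpin as miR-30e-3p had 2097 to 20509 counts. The zeros of overlapping names were therefore not read as absence of the miRNA. All 7 names of the oligodendrocyte-enriched list overlap another name, and none was tested.

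Columns were tied to samples by the sample titles. Totals per library were 1006861 and 673916 counts in Control replicates 1 and 3 and 2809758 and 1858354 in GFP-AGO2 replicates 1 and 3. These are counts assigned to miRNAs; the total number of reads sequenced is not given in the sources used here. Only to see whether replicates were copies of the same library, those of a group were compared by a chi-square test over names with enough counts, with a statistic of 4824 on 478 degrees of freedom for Control and 48060 on 576 for GFP-AGO2. The test counts PCR copies as separate reads, so these values do not measure the spread between mice.

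Changes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the deposited counts, with TMM scaling factors and the filterByExpr filter at a minimum count of 10. This left 457 miRNAs, which held 99.88% to 99.93% of the counts of each library. The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over all miRNAs tested, and a change was called at an adjusted p under 0.05. CPM values are counts divided by the TMM-scaled library size, in the usual CPM unit. A log2 fold change is GFP-AGO2 over Control, with its standard error (SE) from the fit. A share is the percent of a library's miRNA counts. Shares were compared by an exact two-sided permutation test, whose smallest possible p with 2 libraries against 2 is 0.333. The 95% intervals of shares are exact Clopper-Pearson intervals. They cover counting error only, since PCR copies of a molecule are counted as separate reads.

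The 13 miRNA lists, which group names by family, genomic cluster or cell type, were tested where they had tested members, with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between members. P-values were adjusted over the 12 lists with tested members. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction without comparing it with other miRNAs, were alternatives. The lists, the tests and the alternatives were fixed before the data were examined, apart from 2 alternatives named as later choices where they are reported. The matching of miR-9 names to the neuron-enriched list, which at first missed them, was corrected to the list as fixed after the list results had been seen. The miRNAs named were also set by a rule fixed then. It took every tested let-7 5p arm, the 10 miRNAs with the highest mean CPM in GFP-AGO2, the 2 most abundant tested members of each list, and the 10 largest called rises and falls. A rise or fall had to separate both libraries of a group from both of the other and to have a mean of at least 50 counts in the higher group. Names with several positions were kept and are uncertain in their origin. Among the miRNAs named by this rule they are let-7a-5p, let-7c-5p, let-7f-5p, miR-26a-5p, miR-181a-5p, miR-181b-5p, miR-29b-3p, miR-92a-3p, miR-9-3p and miR-124-3p. Other miRNAs named as examples within a list were chosen after their values were seen.

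The alternatives were DESeq2-type size factors, total counts alone, no scaling, no filter, a filter at 50 counts in 2 libraries, removal of names with several positions, the replicate number as a block, removal of each library in turn, the DESeq2 1.42.0 Wald test, a threshold of 2-fold added to the adjusted p, other denominators and members for the let-7 share, and the 20 most abundant miRNAs in place of 10. A fit with 1 library left in a group takes its spread from the other group. A call can therefore be gained or lost in such a fit without a change of value. Positions were taken from the table and set against the GENCODE M21 annotation of the same build; 2034 of the 2035 positions lie inside an annotated miRNA gene on the same strand. In addition, 35 names overlap or copy an annotated RNA of another class, such as a small nucleolar RNA (snoRNA) or a transfer RNA (tRNA), and reads of these names cannot be told from fragments of that RNA.

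The test was checked on simulated counts for the comparison of GFP-AGO2 with Control, with the means and library sizes of the 457 miRNAs and 200 of them changed. The simulated spread depended on abundance alone and was alike in both groups, with as many rises as falls. Over 20 simulations, 43.1% of the 2-fold changes and 83.7% of the 4-fold changes were recovered, and 2.5% of the calls were false. These rates need not hold for the real libraries, where the spread can differ between miRNAs and groups. Scripts ran in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.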

Results

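The data were 4 small RNA libraries, made per the labels after RNA immunoprecipitation for AGO2, from the mouse olfactory bulb, the forebrain region that receives newborn neurons throughout adult life. AGO2 is the Argonaute protein that holds mature miRNAs on their target RNAs. The GFP-AGO2 group (n = 2) came from mice given the vector LV.PGK.GFP-AGO2, whose name gives AGO2 fused to green fluorescent protein, and the Control group (n = 2) from sham-injected mice. Tissue was collected 8 weeks after injection in both groups. The antibody is not given in the sources used here, so the Control libraries may hold RNA bound to the mouse's own AGO2 or only background of the procedure, and each change below is relative to them. The libraries held 673916 to 1006861 miRNA counts in Control and 1858354 to 2809758 in GFP-AGO2, with 714 to 843 miRNA names detected in each. The labels do not say that the libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, which may be technical.

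The comparison of GFP-AGO2 with Control asked which miRNAs the immunoprecipitate of vector-injected mice held in a different proportion, in a study concerned with let-7 in newborn neurons. The miR-200 family and the miR-183 cluster together made up 23.66% ± 0.367 (SD, n = 2) of the miRNA counts in Control. In GFP-AGO2 they made up 3.855% ± 1.765 (SD, n = 2). Of 59 tested miRNAs of the imprinted Dlk1-Dio3 locus 21 rose, among them miR-410-3p and miR-323-3p, by 8.40-fold and 7.27-fold. Another 6 fell, among them the most abundant member, miR-127-3p. The let-7 5p arms were the most abundant family in both groups, at 39.63% ± 1.346 (SD, n = 2) of the counts in Control and 47.49% ± 3.064 in GFP-AGO2. With the miR-200 and miR-183 counts left out of the denominator, a later choice, the shares were 51.91% in Control and 49.37% in GFP-AGO2. The libraries of the groups then overlapped. No let-7 5p arm passed the edgeR test for a change, although some did under other settings. Among the 457 miRNAs tested with edgeR's quasi-likelihood test, 79 rose and 78 fell at an adjusted p under 0.05, of which 58 and 64 changed at least 2-fold. Without Control replicate 1, 47 were called higher and 43 lower, 88 of the 157 calls being kept; without Control replicate 3 they were 49 and 53, with 43 of the 79 rises and 51 of the 78 falls kept. Of the tested miRNAs, 168 had both GFP-AGO2 libraries above both Control libraries and 161 had both below. By chance 33.3% of miRNAs would be separated in this way. All 157 called miRNAs were separated, which largely follows from the call and is no separate support.

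**Figure D1:**
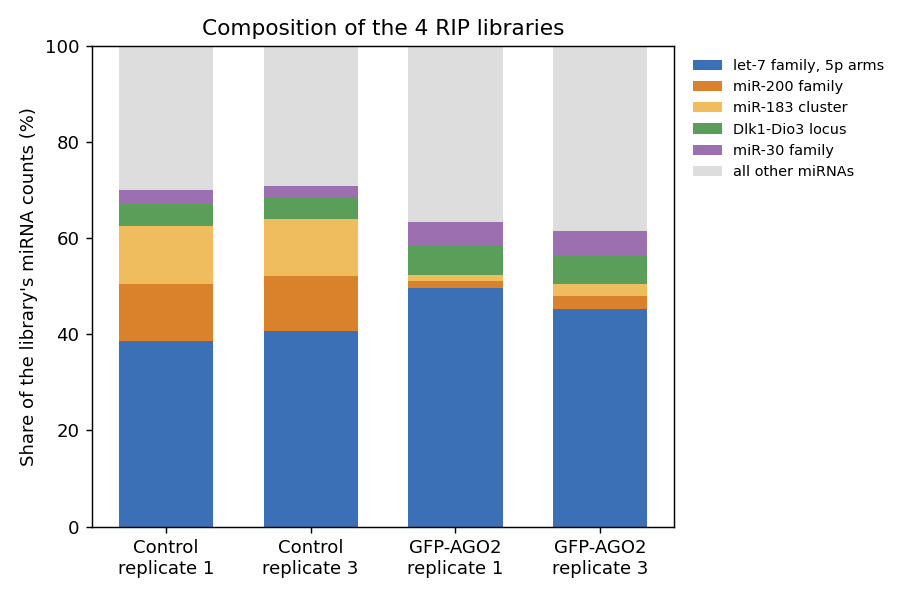
Share of each library's miRNA counts, in percent, held by 5 of the miRNA lists and by all other miRNAs; each bar is 1 library. The miR-200 and miR-183 segments together take 23.92% and 23.4% of the Control libraries and 2.607% and 5.102% of the GFP-AGO2 libraries, and the let-7 segment takes 38.68% to 40.58% in Control and 45.32% to 49.65% in GFP-AGO2.

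All 8 tested members of the miR-200 family and all 5 of the miR-183 cluster fell, with median log2 fold changes of -2.75 and -2.97. The most abundant was miR-183-5p, which fell from 102558 ± 2159 to 13110 ± 5217 CPM (SD, n = 2 each; log2 fold change -2.97, SE 0.30, adjusted p = 0.00353). It lies on chromosome 6 at 30169711 to 30169732 (mm10, minus strand), in an intergenic stretch, beside miR-96-5p at 30169506 to 30169528 and miR-182-5p at 30165962 to 30165986. MiR-182-5p fell by 2.79 (SE 0.35) and miR-96-5p by 3.31 (SE 0.38) on the log2 scale. MiR-182-3p had -3.24 (SE 0.78); it was not called without Control replicate 1 (-2.71, adjusted p = 0.112), and had -2.46 and -4.68 without GFP-AGO2 replicates 1 and 3. From chromosome 4, miR-200a-3p (156054911 to 156054932) fell to 0.147 of its Control level and miR-200b-3p (156055685 to 156055706) to 0.152, both within an intron of Ttll10. The other family members miR-141-3p, miR-429-3p and miR-200c-3p fell by 2.87, 2.96 and 2.64. Where both arms of a hairpin were tested both fell, for miR-200b by 2.73 (5p) and 2.72 (3p). In the same libraries the markers of vessels, blood and immune cells were also lower. They took 0.498% and 0.368% of the counts in the Control libraries and 0.0367% and 0.171% in the GFP-AGO2 libraries. Their list includes miR-126a-3p and miR-142-3p, which overlap another name and were listed at 0. By camera with the preset correlation the miR-200 family had an adjusted p = 0.000223 and the miR-183 cluster an adjusted p = 0.00488, by fry they had 0.0331 and 0.0529, and adjusted over the list alone the counts were likewise 8 and 5. With an estimated correlation both lists had an adjusted p = 0.59, and with no scaling all 13 members still lay below Control, at a median log2 ratio of -1.2, but 3 of each list were called, and miR-182-5p (-1.195), miR-200a-3p (-1.166) and miR-200b-3p (-1.128) were not. Without Control replicate 1 the calls were 7 and 4, and without GFP-AGO2 replicate 3 miR-182-5p, miR-96-5p and miR-200c-3p had -3.38, -3.90 and -3.33, and miR-200b-5p -3.41.

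The let-7 5p arms, which share the family's target-pairing seed sequence, changed little on balance relative to the other miRNAs. Their median log2 fold change was 0.07 over 11 tested members and their camera adjusted p was 0.532, or 0.806 with an estimated correlation and 0.458 by fry. These tests ask for movement in 1 direction. The form of fry that lets members move in either direction gave an unadjusted p = 0.0131. None of the 11 passed the edgeR or the DESeq2 test, nor when adjusted over the list alone; let-7i-5p and let-7a-5p had unadjusted edgeR p-values under 0.05. Let-7b-5p and let-7c-5p were the most abundant miRNAs in every library. Let-7b-5p (chromosome 15, 85707325 to 85707346, in an exon of Lncppara) had 123564 ± 9956 CPM in Control and 120061 ± 13601 in GFP-AGO2 (SD, n = 2; log2 fold change -0.04, SE 0.13). Let-7c-5p, which has several positions and so an uncertain origin, had 115353 ± 9152 and 129937 ± 6822 CPM (log2 fold change 0.17, SE 0.12). The largest difference among the abundant members was that of let-7i-5p (chromosome 10, 122985698 to 122985719), at 0.46 (SE 0.14, adjusted p = 0.0554); let-7a-5p, with several positions, had -0.33 (SE 0.12, adjusted p = 0.0979). The values of let-7f-5p, let-7d-5p, let-7e-5p, let-7g-5p, let-7k, let-7j and miR-98-5p lay between -0.18 and 0.91, with adjusted p-values of 0.263 to 0.866. Leaving out GFP-AGO2 replicate 3 gave let-7i-5p, let-7f-5p and let-7c-5p values of 0.60, 0.36 and 0.22 and let-7a-5p -0.26. Without GFP-AGO2 replicate 1 let-7i-5p had 0.31 and let-7a-5p -0.40. All of these were past the threshold, but both fits take their spread from the Control libraries alone. With no scaling, which moved the median of all miRNAs by 1.66, the let-7 median was 1.78 and all 11 members were called higher; total counts alone called let-7i-5p (0.67) and let-7c-5p (0.39) higher. With no filter let-7i-5p (0.70), let-7f-5p (0.44) and miR-98-5p (0.58) were called higher, without names of several positions let-7i-5p was (0.47), and with the filter at 50 counts let-7a-5p was called lower (-0.48).

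As a share of counts, let-7 5p arms took 38.68% of Control replicate 1 (95% exact interval 38.58 to 38.77) and 40.58% of Control replicate 3 (40.46 to 40.7), against 49.65% (49.59 to 49.71) and 45.32% (45.25 to 45.39) of GFP-AGO2 replicates 1 and 3. The difference of 7.857 percentage points exceeded the SD within either group, and the exact permutation test gave its smallest possible value, p = 0.333. Leaving the miR-200 and miR-183 counts out of the denominator was a choice made after the data were seen. The share was then 51.91% ± 1.514 (SD, n = 2) in Control and 49.37% ± 2.281 in GFP-AGO2. This difference of -2.538 points had the other sign, but the groups overlapped (exact permutation p = 0.667). The Control libraries had 50.84% and 52.98%, and GFP-AGO2 replicates 1 and 3 had 50.98% and 47.76%. From the let-7 precursors, 3 of the 9 tested 3p arms rose and none fell. They were let-7d-3p, from 5331 ± 202 to 13798 ± 582 CPM (log2 fold change 1.37, SE 0.12, adjusted p = 0.00267), let-7a-1-3p (1.07, SE 0.16) and let-7e-3p (1.52, SE 0.28). Let-7d-5p, the partner arm of let-7d-3p in an exon of 6720427I07Rik on chromosome 13 (48536078 to 48536099), had a log2 fold change of -0.18 (SE 0.11, adjusted p = 0.27). The camera adjusted p of the 3p list was 0.184, and 0.59 with an estimated correlation; by fry it was 0.0319, and adjusted over the list alone 3 rose and none fell. Let-7a-1-3p was not called without Control replicate 1 (1.11, adjusted p = 0.0554) or Control replicate 3 (1.05, adjusted p = 0.0576).

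**Figure D2:**
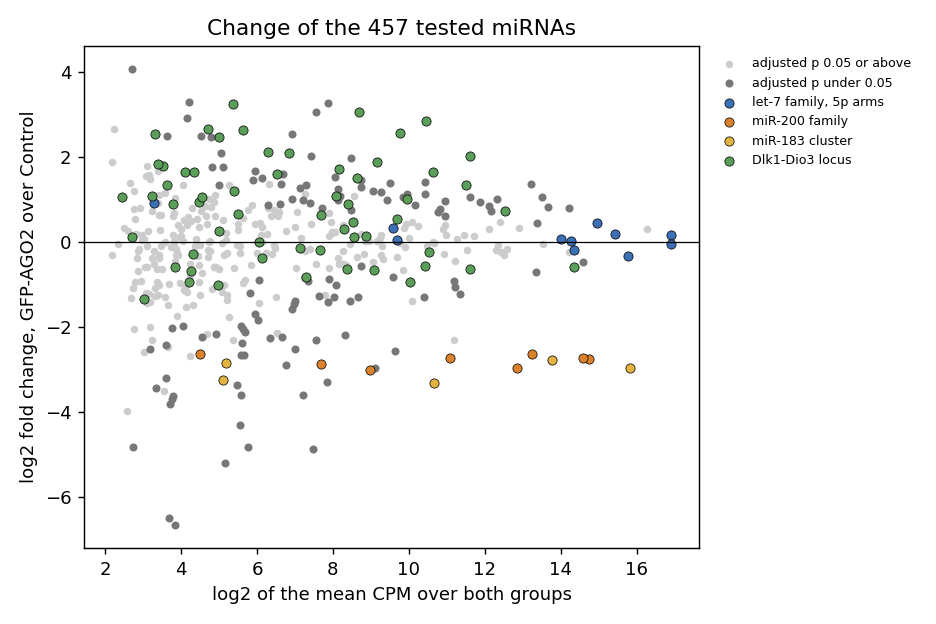
Log2 fold change of GFP-AGO2 over Control against the log2 of the mean CPM over both groups for the 457 tested miRNAs. Each point is 1 miRNA; members of 4 lists are coloured whether or not they passed the test. The 13 miR-200 and miR-183 members lie between -3.31 and -2.62 at all levels, and the 11 let-7 5p arms between -0.33 and 0.91.

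The Dlk1-Dio3 locus, an imprinted cluster on chromosome 12 whose miRNAs are abundant in neurons, had members that moved in both directions. Of 59 tested members, 21 rose, 6 fell and 32 did not pass the test, with a median log2 fold change of 0.91; adjusted over the list alone, 26 rose and 7 fell. The camera adjusted p was 0.00024 in the upward direction, but 0.59 with an estimated correlation; fry gave an adjusted p = 0.0317. MiR-410-3p (109743764 to 109743784, in an exon of Mirg) rose from 88.2 ± 1.29 to 741 ± 118 CPM (SD, n = 2; log2 fold change 3.07, SE 0.20, adjusted p = 0.00249). MiR-323-3p (109712558 to 109712578) rose from 335 ± 40.1 to 2445 ± 249 CPM, and miR-495-3p (109718795 to 109718816) by 2.57 (SE 0.26). MiR-380-5p, miR-329-3p and miR-376b-3p had log2 fold changes of 3.25, 2.68 and 2.65, from 7.06, 6.94 and 13.3 CPM in Control. The value of miR-380-5p rests on 12 and 1 counts in the Control libraries and was 5.50 without Control replicate 1 and 2.54 without Control replicate 3. The most abundant member, miR-127-3p (109592888 to 109592909), fell from 24922 ± 435 to 16671 ± 227 CPM (log2 fold change -0.58, SE 0.11, adjusted p = 0.0138), whereas its neighbour miR-433-3p (109591781 to 109591802) rose by 0.74 (SE 0.13). MiR-127-3p was not called with total counts alone (-0.365, adjusted p = 0.0575), with no filter (-0.339, adjusted p = 0.187) or with the replicate number as a block. Without Control replicate 1 neither miR-127-3p (-0.51, adjusted p = 0.263) nor miR-433-3p (0.85, adjusted p = 0.0912) was called, nor without Control replicate 3 (-0.64 and 0.65, adjusted p = 0.173 and 0.14). With total counts alone 26 members were called higher and 1 lower, and with no scaling 45 and 0, so that miR-127-3p was then at 1.09. Of the 21 rises and 6 falls, 16 and 0 were kept without Control replicate 1, and 16 and 1 without Control replicate 3.

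Markers of vessels, blood and immune cells were lower as a list, with 4 of 7 tested members falling, 6 of 7 when adjusted over the list alone, and a median log2 fold change of -2.38 (camera adjusted p = 0.0064; adjusted p = 0.59 with an estimated correlation; fry adjusted p = 0.106). The list has 23 names. Among them miR-126a-3p and miR-142-3p overlap another name and were listed at 0, so the list may undercount these cells. The median was -2 without GFP-AGO2 replicate 1 and -3.18 without GFP-AGO2 replicate 3. The falling members included miR-146a-5p, an immune-regulated miRNA (-2.17, SE 0.53, adjusted p = 0.0281), and miR-451a of red blood cells (-3.63, SE 0.99). The most abundant of the tested markers, miR-143-3p of smooth muscle, had 3894 ± 769 CPM in Control and 796 ± 749 in GFP-AGO2 (SD, n = 2). Its log2 fold change was -2.29 (SE 0.74), with an edgeR adjusted p = 0.0637. Its GFP-AGO2 libraries lay far apart, at 267 and 1325 CPM. It was called with DESeq2 (-2.317, adjusted p = 0.0489), with no filter (-2.067) and with the replicate number as a block. Its log2 fold change was -1.56 without GFP-AGO2 replicate 1 and -3.87 without GFP-AGO2 replicate 3. These 2 fits leave the gap between the GFP-AGO2 libraries out of the spread, so a call in them is no support. The values of miR-146a-5p and miR-451a were -1.57 and -2.64 without GFP-AGO2 replicate 1 and -3.18 and -5.90 without GFP-AGO2 replicate 3. Neither was called without Control replicate 1 (-2.02 and -3.84, adjusted p = 0.0869 and 0.0932) or Control replicate 3 (-2.33 and -3.42, adjusted p = 0.0573 and 0.109), where 1 of the 4 calls was kept each time, and miR-146a-5p was not called with no scaling (-0.652).

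Neuron-enriched miRNAs showed little common movement, with 3 of 21 tested members rising, 1 falling and a median of 0.18 (camera adjusted p = 0.532; fry adjusted p = 0.356); adjusted over the list alone, 1 rose and 1 fell. MiR-9-5p and miR-9-3p, arms of a miRNA of neural progenitors and neurons, rose by 1.14 (SE 0.21) and 1.07 (SE 0.26), and miR-138-5p fell by 0.82 (SE 0.14). MiR-124-3p, the classic neuronal miRNA, had 6449 ± 1175 CPM in Control and 5793 ± 730 in GFP-AGO2 (log2 fold change -0.15, SE 0.18, adjusted p = 0.555). MiR-9-3p and miR-124-3p have several positions, and miR-9-5p, the partner arm of miR-9-3p, is likewise uncertain in its origin. Without names of several positions, 1 of 13 tested members of this list rose and 1 fell. In the miR-30 family, 4 of 10 tested members rose and 1 fell, with a median of 0.47 (camera adjusted p = 0.175; fry adjusted p = 0.0317) and the same counts adjusted over the list alone. Its most abundant member, miR-30d-5p (chromosome 15, 68341257 to 68341278), rose from 13959 ± 284 to 24282 ± 438 CPM (log2 fold change 0.80, SE 0.11, adjusted p = 0.00687), miR-30e-5p rose by 1.02, miR-30a-5p had 0.34 (adjusted p = 0.0887), and miR-30c-2-3p fell by 1.41. In the miR-17~92 cluster and its paralogs, 4 of 13 rose and none fell, with a median of 0.45 (camera adjusted p = 0.0628; fry adjusted p = 0.158), and 3 rose when adjusted over the list alone. The most abundant tested member was miR-92b-3p, at 1.06 (SE 0.30, adjusted p = 0.0462), with 15622 ± 5595 CPM in GFP-AGO2, while miR-92a-3p had 0.30 (adjusted p = 0.142). The highest log2 fold change in this list was 1.34. MiR-92b-3p was not called with the filter at 50 counts (0.912). Nor was it called without names shared with other RNAs or names (1.024), an alternative added after the data were seen. MiR-30a-5p and miR-92a-3p were called higher with total counts alone (0.554 and 0.521) and no filter (0.578 and 0.544), and miR-30a-5p without GFP-AGO2 replicate 1 (0.39). Without either Control library no rise of a neuronal, miR-30 or miR-17~92 member was kept, except that of miR-9-3p without Control replicate 3. Without GFP-AGO2 replicate 1, 3 neuronal members were called lower, and with no scaling no member of these lists was called lower. Values without Control replicates 1 and 3, none called, were 1.306 and 1.006 for miR-9-5p, -0.79 and -0.84 for miR-138-5p, 0.83 and 0.78 for miR-30d-5p, 1.045 and 1.007 for miR-30e-5p and 0.88 and 1.28 for miR-92b-3p. MiR-9-3p had 0.80 without Control replicate 1, where it was not called.

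In the miR-181 family, 3 of 8 tested members rose and 1 fell; adjusted over the list alone, 3 rose and 2 fell. The median was 0.14 and the mean 0.65 (camera adjusted p = 0.416; fry adjusted p = 0.0529). The 3p arms miR-181b-1-3p and miR-181a-1-3p rose by 2.93 (SE 0.68) and 2.02 (SE 0.18). The value of miR-181b-1-3p rests on 2 and 4 counts in Control replicates 1 and 3. By contrast, the abundant miR-181a-5p fell from 28623 ± 700 to 20754 ± 2.27 CPM (SD, n = 2). Its log2 fold change was -0.46 (SE 0.11, edgeR adjusted p = 0.0275), and miR-181b-5p had -0.04. MiR-181a-5p was not called with total counts alone (-0.247), with no filter (-0.222) or with the replicate number as a block. Nor was it called without Control replicate 1 (-0.43) or Control replicate 3 (-0.48). MiR-181b-1-3p had 2.26 without Control replicate 1, no longer called, and 3.81 without Control replicate 3; of the 3 rises 1 was kept without Control replicate 1. In the miR-29 family 1 of 5 fell, miR-29c-3p at -1.19 (SE 0.29), and miR-29a-3p and miR-29b-3p had -0.31 and -0.17 (median -0.31, camera adjusted p = 0.184, fry adjusted p = 0.161). MiR-29a-3p was called lower with the filter at 50 counts (-0.461) and without GFP-AGO2 replicate 3 (-0.38). In the ependymal and choroid plexus list, 1 of 5 rose, miR-204-5p (chromosome 19, 22750610 to 22750631, in an intron of Trpm3) at 0.74 (SE 0.14), and miR-204-3p had -0.16; the list median was 0.27 (camera adjusted p = 0.646; fry adjusted p = 0.462), or -0.30 without Control replicate 1. Adjusted over the list alone, the miR-29 and ependymal counts were the same. MiR-204-5p was not called without Control replicate 1 (0.84) or Control replicate 3 (0.65). With no scaling the miR-29 median turned to 1.34, and miR-181a-5p to 1.22, and miR-29c-3p was not called without GFP-AGO2 replicate 1 (-1.003), Control replicate 1 (-1.13) or Control replicate 3 (-1.23). The oligodendrocyte-enriched list had no tested member. All 7 of its names overlap another name, and reads lost to overlap cannot be told here from low expression.

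**Figure D3:**
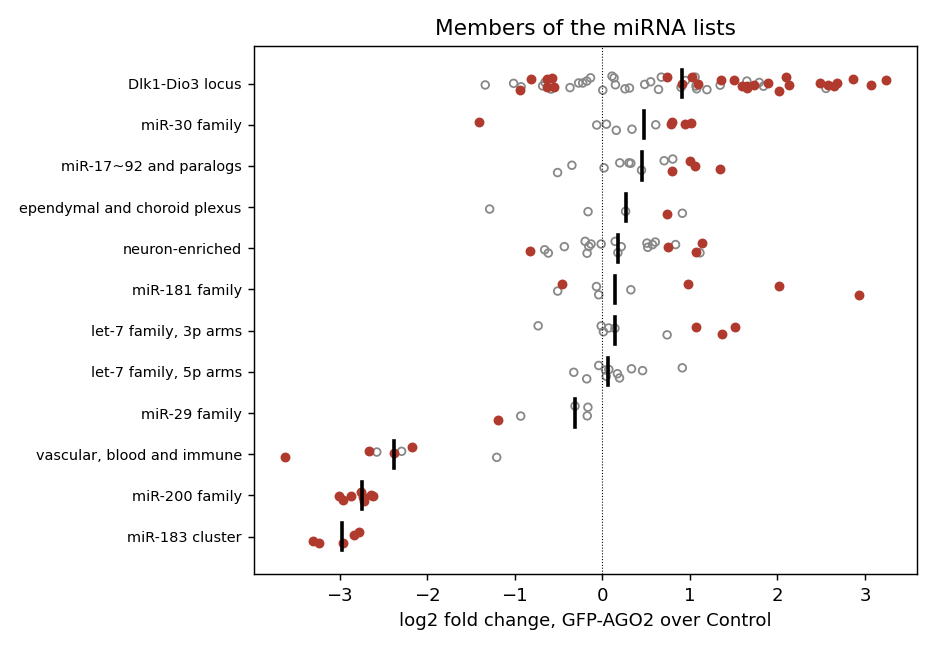
Log2 fold change of GFP-AGO2 over Control for each tested member of the 12 lists. Filled points had an adjusted p under 0.05, open points did not, and the black bar is the list median. The medians run from -2.97 in the miR-183 cluster to 0.91 in the Dlk1-Dio3 locus.

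Outside the lists, miR-676-5p (X chromosome, 100381114 to 100381135, in an intron of Eda) rose by 3.06 (SE 0.22), from 39.7 ± 7.09 to 336 ± 23.8 CPM (SD, n = 2). MiR-7a-2-3p (chromosome 7, 78888335 to 78888356) rose by 3.29 (SE 0.81) from 1 and 4 counts in the Control libraries to 127 and 49; it had 2.40 without Control replicate 1, no longer called, and 4.90 without Control replicate 3. MiR-1983, which overlaps the tRNA gene n-TItat14 on chromosome 13, also rose by 3.29 (SE 0.25). Several of the largest falls were of names that lie on a snoRNA. MiR-5121 on Snord33 (chromosome 7, 45126925 to 45126945, in Rpl13a) fell by 5.20 (SE 0.42), miR-1291 on Snora34 had a log2 fold change of -4.81 (SE 0.87), miR-3535 on a snoRNA within Ncl of -3.59 (SE 0.50) and miR-1940 on Snora47 of -3.37 (SE 0.52). Other large falls were those of miR-5099 (-4.86, SE 0.52), miR-6240 (-4.29), miR-5114 (-3.60) and miR-6236 (-3.29). Several of the largest falls rest on few counts in GFP-AGO2 replicates 1 and 3. These were 5 and 4 for miR-5121, 2 and 15 for miR-1291, 8 and 25 for miR-5114, and 11 and 11 for miR-6240. The sizes of these falls are therefore uncertain. Without GFP-AGO2 replicate 1, miR-1291, miR-3535 and miR-5114 had -3.83, -2.99 and -2.83. Without GFP-AGO2 replicate 3 they had -7.13, -4.49 and -4.98, and miR-5099 -5.58. The -7.13 of miR-1291 rests on 2 counts in GFP-AGO2 replicate 1. MiR-5114 was not called without Control replicate 3 (-3.25). Of the 19 tested names that overlap or copy another RNA class, 6 fell and 1 rose, with a median of -0.53.

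The most abundant miRNAs of the GFP-AGO2 libraries were let-7c-5p, let-7b-5p and miR-26a-5p, a miRNA expressed in many tissues. MiR-26a-5p, with several positions, had 70979 ± 498 CPM in Control and 88412 ± 5717 in GFP-AGO2 (SD, n = 2; log2 fold change 0.32, SE 0.11, adjusted p = 0.0772). It was called higher with total counts alone (0.532), no filter (0.559), without GFP-AGO2 replicate 1 (0.25) and without GFP-AGO2 replicate 3 (0.38). MiR-183-5p had rank 3 in both Control libraries, at 9.65% and 9.36% of the counts, and was not among the 10 most abundant in either GFP-AGO2 library. The 10 most abundant miRNAs of each library held 61.28% ± 0.594 (SD, n = 2) of the counts in Control and 59.89% ± 3.21 in GFP-AGO2, a difference within the spread of GFP-AGO2 (exact permutation p = 1) that turned to 0.88 points without GFP-AGO2 replicate 3.

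Fewer miRNAs were called when a Control library was left out. Such a fit takes its spread from the GFP-AGO2 libraries alone, so a lost call need not mean a changed value. Of the miRNAs named above by the fixed rule, 12 lost their call without Control replicate 1 (adjusted p = 0.0554 to 0.337). Without Control replicate 3, 9 did so (adjusted p = 0.0573 to 0.291). With no scaling for library size 264 were called higher and 20 lower, so that 93% of calls were higher against 50.3%.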

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

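The alternatives below were fixed before the data were examined, except the removal of names shared with other RNAs or names and the let-7 denominator without the miR-200 and miR-183 lists, which were added after seeing the data. Of 54 named miRNAs, 18 kept their direction and their side of the threshold under every alternative run and 4 more under all but no scaling. The counts of 79 higher and 78 lower became 264 and 20 with no scaling, and ran from 47 to 94 higher and 43 to 106 lower when each library was left out in turn, with the fewest without a Control library. They were 75 and 82 with DESeq2, 118 and 84 with no filter, and 100 and 66 with total counts alone, which moved the median by 0.21. Of the 157 calls, 145 were kept with DESeq2, 145 with total counts alone and 99 with no scaling. Replicates numbered alike did not deviate together (correlation -0.061), so the numbers were not read as pairs; with the replicate block 79 were higher and 85 lower, miR-127-3p and miR-181a-5p were not called, and miR-143-3p was (-2.692).

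By construction, no scaling moved all miRNAs up by a median of 1.66 and reversed let-7a-5p (1.38), let-7b-5p (1.675), let-7d-5p (1.504), miR-124-3p (1.59), miR-127-3p (1.09), miR-181a-5p (1.22), miR-181b-5p (1.66), miR-204-3p (1.52), miR-29a-3p (1.34) and miR-29b-3p (1.497). Total counts alone reversed let-7b-5p (0.175), let-7d-5p (0.037), miR-124-3p (0.064), miR-181b-5p (0.172), miR-204-3p (0.058) and miR-29b-3p (0.046), and no filter reversed these too, at 0.202, 0.063, 0.091, 0.202, 0.077 and 0.067. The filter at 50 counts reversed let-7e-5p (-0.077), let-7g-5p (-0.115) and let-7k (-0.106), and leaving out shared names reversed let-7g-5p (-0.001). With each library left out in turn, let-7b-5p ran from -0.162 to 0.07, let-7g-5p from -0.053 to 0.119, let-7k from -0.027 to 0.112, miR-124-3p from -0.289 to 0.009 and miR-181b-5p from -0.195 to 0.096. All but let-7a-5p, miR-127-3p, miR-181a-5p and miR-29a-3p had main values within 0.2 of 0.

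The 1 list called higher and 3 lower became 0 and 0 with an estimated correlation, 3 and 1 with fry, 4 higher with no filter and 1 lower with the filter at 50 counts; left-out libraries gave 1 to 2 higher. That filter also turned the direction of the let-7 5p (adjusted p = 0.767), neuron-enriched and ependymal lists (0.896 each), and the ependymal list turned without Control replicate 1, with an adjusted p from 0.429 to 0.983 over left-out libraries; the cause was not tested. The let-7 difference of 7.86 points became -2.54, with overlapping groups, without the miR-200 and miR-183 counts, since those counts fell. With all counts in the denominator the let-7 difference ran from 5.69 to 10.02 over left-out libraries. The difference of -1.39 in the top 10 share ran from -3.66 to 0.88. Total reads sequenced are unknown, and the smaller Control totals limit what can be called among rare miRNAs.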

Other observations

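The miRNAs in this part outside the fixed lists were chosen after their values were seen, and so were all tests here except that of fragments of other RNAs.

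The paralogs miR-221-3p and miR-222-3p, both linked to cell proliferation, rose in GFP-AGO2 by 1.13 (SE 0.14) and 0.84 (SE 0.14), and miR-101a-3p and miR-101b-3p by 0.96 and 0.98 (SE 0.16 each). In the miR-99b, let-7e and miR-125a cluster, miR-99b-5p rose by 0.83 (SE 0.12) and miR-125a-5p by 0.45 (SE 0.12), and let-7e-5p had 0.07 (SE 0.13, adjusted p = 0.705). Among the falls, miR-375-3p, abundant in endocrine and epithelial cells, went from 1357 to 231 CPM (log2 fold change -2.56, SE 0.33), miR-184-3p fell by 2.31 (SE 0.31), miR-378a-3p by 1.29 (SE 0.21) and miR-22-3p by 1.04 (SE 0.18). All of these but let-7e-5p had an edgeR adjusted p under 0.05. Not called without Control replicates 1 and 3 were miR-222-3p (0.78 and 0.92), miR-99b-5p (0.92 and 0.75) and miR-125a-5p (0.56 and 0.35), and without Control replicate 3 miR-101a-3p (0.80), miR-101b-3p (0.83) and miR-22-3p (-0.97). Without scaling, the mean counts of miR-378a-3p and miR-22-3p were higher in GFP-AGO2.

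Of 21 pairs of 5p and 3p arms in which both arms were called, 8 had both arms higher, 9 both lower and 4 in opposite directions. The opposite pairs were miR-323 (-0.82 for the 5p and 2.86 for the 3p arm), miR-30c (0.95 and, for miR-30c-2-3p, -1.41), and miR-181a-5p (-0.46) with each of its 3p arms miR-181a-1-3p (2.02) and miR-181a-2-3p (0.98). None of these 4 pairs kept both calls without Control replicate 1 or Control replicate 3: miR-181a-5p (-0.43 and -0.48), miR-323-5p (-0.84 and -0.79) and miR-30c-5p (0.89 and 1.03) were then not called. Without Control replicate 1 miR-181a-2-3p (0.97) was not called either, nor miR-323-5p without GFP-AGO2 replicate 1 (-0.77). Of all 21 pairs, 5 kept both calls without Control replicate 1 (1 higher, 4 lower) and 6 without Control replicate 3 (1 higher, 5 lower). The 5p arms of miR-30c and miR-181a have several positions, so each can also come from a second hairpin. The let-7d arms and the miR-181a pairs prompted the hypothesis that less abundant arms rise against their partners in GFP-AGO2, although in the miR-323 and miR-30c pairs the less abundant arm fell. The test run for it decides nothing. Over 109 hairpins with both arms tested, the median change of log2 minor over major arm was 0.01 (SD 1.37), and in the 41 whose minor arm had a mean of at least 100 counts it was -0.04 (SD 1.22). The minor arm was chosen by its mean over the 4 libraries, which the change itself moves, and in 8 of the 109 it was the more abundant arm in Control. The minor arm rose against its partner in 55 of the 109 (permutation test, p = 0.519) and in 20 of the 41 (permutation test, p = 0.918). A split at 100 counts in every library, tried before this, gave -0.46 (SD 1.04) in 23 hairpins. There the minor arm rose in only 5 of the 23 (permutation test, p = 0.00519), opposite to the hypothesis. This split has the same fault, with 3 of the 23 minor arms more abundant in Control. None of the splits showed a general rise, but because of this fault the question stays open.

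The joint fall of the miR-200 family and the miR-183 cluster was weighed against technical explanations; scaling between libraries as the whole cause is argued against by the unscaled counts, whose median log2 ratio over the 13 members was -1.2 (SD 0.24). A background of RNA in the Control immunoprecipitate, shared with fragments of other RNAs, may contribute: the 19 tested names that overlap another RNA class had a median of -0.53 (SD 2.16), against -2.83 (SD 0.21) for the 13 members. That difference of 2.31 exceeds the larger SD, 2.16, which had been set beforehand as evidence against it, but the criterion was ill chosen, since the class mixes snoRNA fragments with other miRNAs, 6 fell (from -2.24 to -5.20) and 1 rose, so the median decides nothing. For vascular and blood cells in the Control tissue the comparison decides nothing, since a similar fold does not show a shared source. Their 7 tested markers, of 23 names, had a median of -2.38 (SD 0.72), within that SD of the 13 members. Without GFP-AGO2 replicate 3 their median was -3.18. In Control, miR-143-3p had 3894 and miR-146a-5p 517 CPM. The marker list held 0.433% of the Control counts, against 23.66% for the miR-200 and miR-183 lists. Markers that overlap another name may be undercounted. The design's own difference, AGO2 of vector-bearing cells against the immunoprecipitate of a sham-injected bulb, was not tested, as no input RNA was used here. Nor was it tested which cells of the bulb the 13 members came from.

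GFP-AGO2 replicate 3 lay closer to the Control libraries than replicate 1 did, with 5.102% against 2.607% of its counts in the miR-200 and miR-183 lists. A single scale factor between the replicates cannot change shares of counts, and the ratios here were taken after scaling. The comparison run for it is therefore no evidence. In it the 79 miRNAs called higher had a median log2 ratio of replicate 3 over replicate 1 of -0.08 (SD 0.28). The 13 listed members had 0.92 (SD 0.56). A larger share of Control-like RNA in replicate 3 is a candidate explanation. The 65 other miRNAs called lower had a median ratio of 0.42 (SD 0.64), and 57 of the 65 were higher in replicate 3. These values largely restate that replicate 3 lay closer to Control, so they are no separate support. Whether any such RNA came from the tissue or from the immunoprecipitation was not tested.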
